A study of Mus musculus with 8 samples.

How the data were processed

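RNA was measured in 8 libraries of mouse ovarian granulosa cells, the somatic cells that surround the oocyte in a follicle. The labels gave total RNA from female C57BL/6 animals, extracted with Trizol, and named both a TruSeq and a TruePrep library kit and paired-end Illumina sequencing. The groups were wild type (WT) and CNOT6/6L knockout (KO), each untreated (0 h) or 44 h after PMSG, a gonadotropin with FSH-like activity, with 2 libraries per group. The labels gave no PMSG dose and did not state whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

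The authors deposited 1 table of FPKM values (fragment numbers scaled to transcript length and library size) with a column per library and 23235 gene symbols, per the file headers. TopHat2 2.1.1, Cufflinks 2.2.1 and the mm9 build were named per the submitters' processing notes, with no role or order; the gene annotation and any filter are not given in the sources used here. The reference gene table used here was of another assembly, GRCm38.p6, so no coordinates are printed, and that table served only for gene names and for which chromosome the genes of one list share. FPKM are not counts, and no count model was used. The relative depth of the libraries was taken from the steps between low FPKM values, and it ranged from 0.904 to 1.25, where 1 is the median library. FPKM sums ranged from 675557 to 753216. An FPKM of 0 may be a failed estimate, so such genes are described as listed at 0.

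Values were analysed as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with an FPKM of at least 1 in at least 2 libraries were kept (13688 of 23235). A model with a mean for each of the 4 groups was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided), with 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested within each of 5 comparisons, and genes were called at an adjusted p under 0.05. The comparisons were KO against WT at 0 h, KO against WT at 44 h, 44 h against 0 h in WT, 44 h against 0 h in KO, and the difference between the last 2 (the interaction). Standard errors (SE) are those of the limma fit.

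Before the data were examined, 28 gene lists were fixed, together with the tests, the alternatives and the rule for naming genes. A list of mitochondrially encoded genes had no member in the table, and 27 lists with at least 4 tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as the alternative. Named genes were, per comparison, the called genes with a group mean FPKM of at least 5, no overlap between the libraries of the groups and a symbol that is not a predicted, clone or short RNA name, at most 10 in each direction. Cnot6 and Cnot6l were named in each comparison, as were up to 4 members of each list with the smallest p, whether or not they passed. Genes named for other reasons are marked as chosen after their values were seen. For genes lowered or raised by PMSG, genes were chosen by a change of at least 1 (log2) in a WT library pair and measured in the other WT pair and in KO, in both directions, so that choice and measurement in WT did not share libraries.

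The scripts were tested on simulated data. For 44 h against 0 h in WT over 13688 genes, 26 of 67 genes changed by 1 (log2) were recovered, 65 of 67 changed by 2 and 65 of 66 changed by 3, with 12 false calls. The simulated libraries of a group were drawn with equal spread, unlike the KO libraries at 44 h described in the results. All 5 lists shifted by 0.5 were called, and 0 of the unshifted lists, with either correlation setting. Simulated genes varied independently of each other, whereas the correlation estimated in the data was 0.77 for the oocyte markers. The simulation therefore did not test whether the preset correlation of 0.01 suits these lists. Alternatives covered the pseudocount, the filter on low values, the size of the PMSG change and the pairing used to choose genes, quantile and median-of-ratios scaling, a replicate block, fits over only the groups compared, robust empirical Bayes and leaving out each library in turn. A fit without short RNA gene entries was added after seeing the data.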

Results

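Granulosa cell transcriptomes were compared between genotypes and between untreated cells and cells taken 44 h after PMSG, in 8 libraries (4 groups, n = 2 each). The series title places the study around CNOT6/6L, deadenylase subunits of the CCR4-NOT complex that shortens mRNA poly(A) tails, and the degradation of mRNA during follicle growth. Cyp11a1, which starts steroid synthesis from cholesterol, already separated the libraries: it was 4451 and 4339 FPKM in WT at 44 h, 2508 in KO replicate 2 and 129 in the library labelled KO replicate 1 at 44 h. On an axis from the WT 0 h mean (0) to the WT 44 h mean (1), the 2 KO libraries at 44 h lay at 0.213 (replicate 1) and 1.03 (replicate 2). At 0 h the KO libraries lay at -0.163 and -0.356 and the WT libraries at 0.123 and -0.123. Positions on this axis are thus not changes from the KO 0 h level. Between those 2 libraries 1527 genes were at least 2-fold apart, against 317 in WT at 0 h, 382 in WT at 44 h and 432 in KO at 0 h. The relative depth was 0.904 and 0.996 in WT at 0 h, 1.03 and 0.970 in WT at 44 h, 1.00 and 0.958 in KO at 0 h and 1.00 and 1.25 in KO at 44 h, in replicate order. Every count that uses the pooled spread includes this pair.

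The targeted genes were read first. Cnot6 was 29.1 and 18.4 FPKM in WT at 0 h and 11.7 and 12.0 in KO at 0 h, a difference of -0.91 (log2, SE 0.269, limma adjusted p = 0.396). At 44 h Cnot6 was 26 and 26.9 in WT, 17.4 in KO replicate 2 and 26.7 in the library labelled KO replicate 1, which lay within the WT range. The difference at 44 h was -0.28 (SE 0.269, adjusted p = 0.723), and it was 0.011 with replicate 1 as the only KO library. Cnot6l was 6.11 and 7.07 in WT and 4.69 and 1.97 in KO at 0 h (-0.88, SE 0.343, adjusted p = 0.487), and 4.2 and 2.63 in WT and 2.01 and 1.61 in KO at 44 h (-0.63, SE 0.343, adjusted p = 0.564). Neither gene passed the test at either time, and whole-gene FPKM need not reach 0 where part of a gene is deleted.

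**Figure D1:**
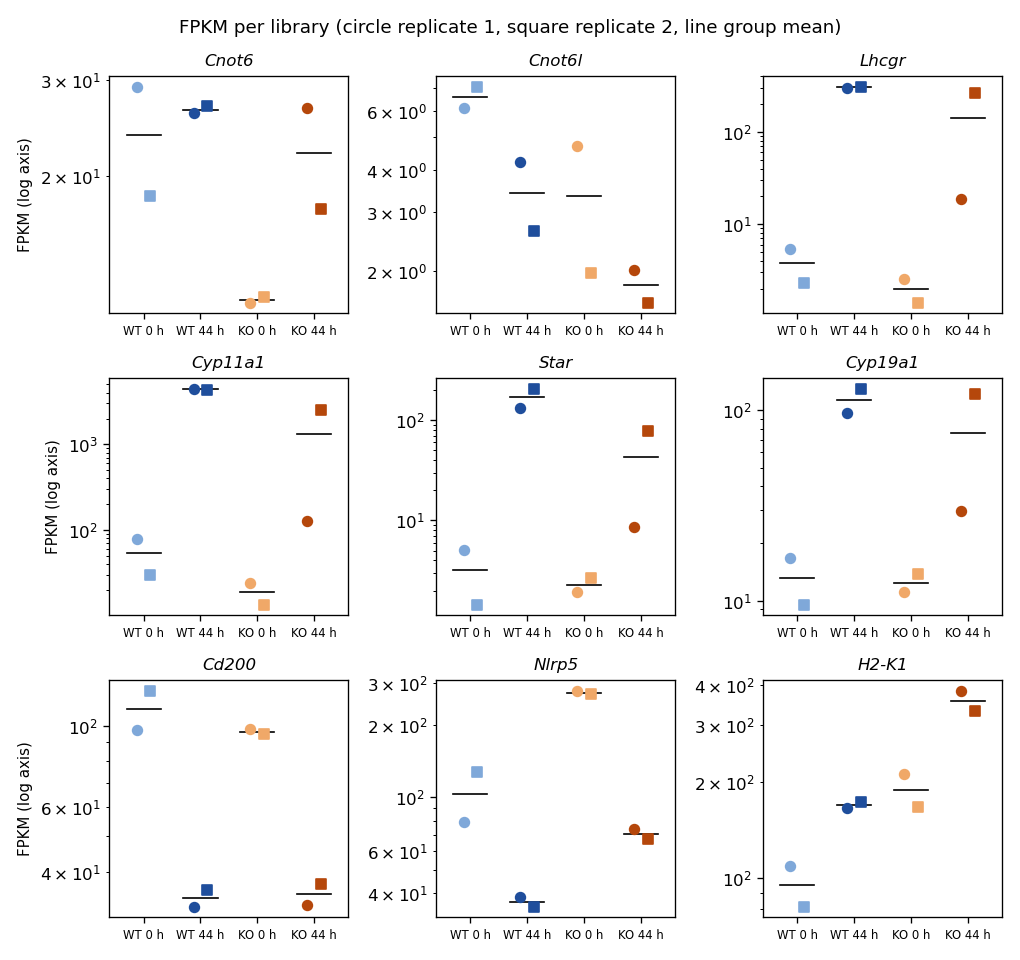
FPKM of 9 genes in each library on log axes, by genotype and time; circles are replicate 1, squares replicate 2 and lines group means (n = 2). Lhcgr was 261 in KO replicate 2 and 18.8 in the library labelled KO replicate 1 at 44 h, whereas Cd200 was 37.2 and 32.6 in the same libraries.

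Without PMSG, oocyte transcripts and mitotic transcripts lay higher and sterol enzymes lower in KO than in WT. All 25 oocyte markers were higher in KO (median 0.93, log2). Nlrp5, an oocyte maternal-effect gene, was 273 ± 6.39 FPKM in KO and 103 ± 34.5 in WT (SD, n = 2). Ddx4, a germ cell RNA helicase, was 15.8 ± 3.6 and 5.24 ± 2.02. Cholesterol synthesis genes had a median of -0.53 (20 of 23 lower). Steroidogenesis genes had a median of -0.28 (18 of 24 lower). Hmmr, a spindle-associated gene, was 108 ± 16.8 in KO and 49.2 ± 10.6 in WT, within a G2/M list of median 0.19 (34 of 40 higher). Whether oocyte RNA enters the cell cycle differences here, at 44 h or in the interaction was not tested. Among markers of other tissues, surface epithelium markers had a median of -0.57 (8 of 10 lower, camera adjusted p = 0.121) and oviduct and ciliated markers of 1.27 (6 of 7 higher, adjusted p = 0.455), neither of them called. Immune markers had a median of 0.57, but this was 1.61 in KO replicate 1 and -0.35 in KO replicate 2 relative to the WT 0 h mean.

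Camera called 7 of the 27 lists between genotypes at 0 h with the preset correlation: oocyte markers (adjusted p = 1.18e-13), cholesterol synthesis (2.15e-05), steroidogenesis (0.0174), oxidative phosphorylation (0.0174, median -0.086), G2/M (0.0263), immune markers (0.0263) and cytosolic ribosomal proteins (0.0438, median -0.078, 0 after quantile normalization). With an estimated correlation none was called (adjusted p = 0.929 for each). The other 20 lists had adjusted p of 0.0822 to 0.902, CCR4-NOT subunits among them (median 0.084). Adjusted over the list alone, 16 of the oocyte markers, 1 G2/M gene (Hmmr) and 1 oxidative phosphorylation gene (Cox8c, listed at 0 in both WT groups) passed, and 0 of the cholesterol synthesis or steroidogenesis genes. Over all genes tested, 0 members of these lists did. Limma called 5 genes in all (2 higher, 3 lower), with 1326 at an unadjusted p under 0.05 where 684 were expected by chance. Of the 5, Fetub, a secreted protease inhibitor, was 86.2 ± 11 in KO and 22.3 ± 3.69 in WT (1.90, SE 0.167, adjusted p = 0.0223). The others were short RNA entries, and without such entries limma called 0 genes with 1352 at an unadjusted p under 0.05. Fetub lost its call, at 1.74 to 2.07, without either library of WT at 0 h, KO at 0 h or WT at 44 h. Limma called 3 genes without WT replicate 2 at 0 h, 9 without KO replicate 2 at 0 h and 8 without either KO library at 44 h. The steroidogenesis and G2/M calls ended without WT replicate 1 at 0 h (medians -0.15 and 0.061), the G2/M call without KO replicate 2 at 0 h (0.14), and the immune call without KO replicate 1 at 0 h (-0.35) or WT replicate 2 at 0 h (0.41). Without either KO library at 44 h, camera also called the surface epithelium markers, luteal genes (-0.26), FSH-induced genes (-0.19) and unfolded protein response (-0.14) lower at unchanged medians. The oxidative phosphorylation call ended without WT or KO replicate 1 at 0 h (-4.91e-04 and -0.015). Median-of-ratios scaling ended the G2/M call (0.14), quantile normalization those of steroidogenesis (-0.36) and oxidative phosphorylation (-0.028), and both that of ribosomal proteins, which also ended with FPKM of at least 5 in 2 libraries or a replicate block. The immune call ended without a filter or with only the groups compared. The ribosomal call ended without WT replicate 1 (-0.051), KO replicate 1 (-0.083) or KO replicate 2 (-0.083) at 0 h.

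In WT, 44 h of PMSG went with much higher levels of steroid-making and luteal genes and lower levels of oocyte and cell cycle genes. Lhcgr, the LH receptor, was 304 ± 6.32 FPKM at 44 h and 3.80 ± 2.16 at 0 h. Star, which moves cholesterol into mitochondria, was 169 ± 51.6 and 3.24 ± 2.53, and Cyp19a1, the aromatase that makes estrogen, was 113 ± 23.4 and 13.2 ± 5.15. All 24 steroidogenesis genes (median 1.49) and all 23 cholesterol synthesis genes (median 1.06) were higher. Also higher were 16 of 18 luteal genes (2.33), 18 of 22 FSH-induced genes (0.73) and 21 of 27 LH and ovulation genes (0.87). Oocyte markers were lower in 25 of 25 (median -1.20), G1/S genes in 37 of 39 (-0.53) and G2/M genes in 36 of 40 (-0.46), with Gdf9, an oocyte growth factor, at 233 ± 6.24 and 598 ± 206. The median over all genes was -0.13 in this comparison and -0.11 in KO, and it was -0.014 and 0.011 after median-of-ratios scaling.

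Camera called 17 lists in WT, 14 higher and 3 lower. Besides those above they were follicular matrix (median 0.44), theca and stroma markers (0.66), endothelial markers (0.76), surface epithelium markers (0.60), immune markers (0.23), oxidative phosphorylation (0.23), replication-dependent histones (0.28), granulosa identity (0.33) and AU-rich element mRNAs (0.28). None was called with an estimated correlation (adjusted p = 0.39 to 0.732 for the called lists). Without WT replicate 2 at 0 h the granulosa identity (0.31), AU-rich element (0.19), immune (0.074) and surface epithelium (0.46) calls ended. The AU-rich element (-0.17) and immune (-0.013) calls ended without WT replicate 1 at 44 h, and the granulosa identity (0.23) and surface epithelium (0.40) calls without WT replicate 2 at 44 h. Without either KO library at 44 h the granulosa identity and immune calls ended at the same medians, and the oviduct and ciliated markers were called. Median-of-ratios scaling ended the AU-rich element (0.37), histone (0.33), granulosa identity (0.47), immune (0.37) and surface epithelium (0.72) calls. With FPKM of at least 5 in 2 libraries the AU-rich element (-0.060), histone (0.35), immune (0.24) and surface epithelium (0.59) calls ended. The granulosa identity call also ended after quantile normalization (0.31), and it and the AU-rich element call with the WT groups alone. Lists that were not called had medians of -0.25 (CCR4-NOT subunits), -0.26 (other mRNA decay factors), -0.41 (small follicle genes), -0.09 (apoptosis and atresia), -0.065 (immediate-early genes, mean 0.019), -0.22 (TGF-beta family signalling), -0.12 (cytosolic ribosomal proteins), -0.27 (unfolded protein response), -0.013 (erythroid markers, mean 0.066) and 0.81 (oviduct and ciliated markers). Adjusted over the list alone, 14 steroidogenesis genes, 12 luteal genes and 12 FSH-induced genes were higher and 23 oocyte markers, 18 G2/M genes and 13 G1/S genes lower, with 0 of these over all genes tested.

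Limma called 11 genes in WT (7 higher, 4 lower; 3301 at an unadjusted p under 0.05), 3 of them short RNA entries. Mrap, an accessory protein of the melanocortin receptors, rose from 16.4 ± 1.57 to 429 ± 25.6 (4.63, SE 0.502, adjusted p = 0.0417). Cst8, a cystatin, rose from 14.2 ± 1.63 to 303 ± 129 (4.26, SE 0.338, adjusted p = 0.00951), and Slc7a8, an amino acid transporter, rose from 5.86 ± 1.38 to 45.8 ± 11 (2.77, SE 0.220, adjusted p = 0.00951). Ren1, the renin gene, also rose, and Defb36 was 10.01 and 13.1 at 44 h and listed at 0 in both WT libraries at 0 h. Cd200, a surface glycoprotein, fell from 111 ± 19.1 to 33.98 ± 2.42 (adjusted p = 0.0318), and Cables1 and Cntf fell too. With the 4 WT libraries alone, limma called 945 genes (546 higher, 399 lower), among them Lhcgr (adjusted p = 0.00164), Cyp11a1 (0.00381), Star (0.00697) and Cyp19a1 (0.0091). Over all 8 libraries their adjusted p were 0.0776, 0.0839, 0.0776 and 0.0857. Limma called 1333 genes without the library labelled KO replicate 1 at 44 h, 1330 without KO replicate 2 at 44 h, 7 without WT replicate 1 at 0 h and 4 without WT replicate 2 at 0 h.

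In KO, oocyte markers also lay lower at 44 h, and the steroid-making genes were higher but far apart in the 2 libraries. Lhcgr was 1.97 ± 0.791 at 0 h, then 18.8 in the library labelled KO replicate 1 at 44 h and 261 in replicate 2. Star was 2.29 ± 0.497, then 8.61 and 77.7. Against the KO 0 h mean, the median of luteal genes was 0.36 in replicate 1 and 2.59 in replicate 2, that of cholesterol synthesis genes 0.15 and 1.69, and that of FSH-induced genes 0.76 and 0.80. Oocyte markers were lower in 25 of 25 (median -1.25), at -0.91 and -1.70 in the 2 libraries. Theca and stroma markers, cells outside the granulosa layer, were at -0.057 and 0.51, surface epithelium markers at 0.043 and 2.27, and oviduct and ciliated markers at -1.78 and 2.44.

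Limma called 19 genes in KO (10 higher, 9 lower; 2884 at an unadjusted p under 0.05), 4 of them short RNA entries. Saa3, an acute-phase gene, was 1.21 and listed at 0 at 0 h and 44.4 and 71.4 at 44 h. Akr1b7, an aldo-keto reductase, rose from 0.351 ± 0.0663 to 28.4 ± 8.51 (4.41, SE 0.495, adjusted p = 0.0478). Nupr1, a stress-response gene, fell from 479 ± 64.6 to 95.2 ± 29.1 (-2.35, SE 0.243, adjusted p = 0.0473), Lims2 from 43.4 ± 5.08 to 10.5 ± 2.65 and Nlrp5 from 273 ± 6.39 to 70.6 ± 4.94 (-1.94, SE 0.226, adjusted p = 0.0478). Gadd45b, Cntf, Cables1 and Cd200 also fell and Gas7, Ren1 and Defb36 rose. Chi3l3, 4930550L24Rik and Hist2h2ab, named outside the rule after their values were seen, were called too. Without the library labelled KO replicate 1 limma called 1169 genes, and without replicate 2 it called 32. It called 3 without KO replicate 2 at 0 h, and 8 without KO replicate 1 at 0 h or either WT library at 44 h. Camera called 13 lists, 12 higher and the oocyte markers lower (adjusted p = 9.56e-12). The medians were 1.29 for steroidogenesis, 0.82 for cholesterol synthesis, 1.63 for luteal genes, 0.77 for FSH-induced genes, 0.24 for theca and stroma markers, 1.38 for surface epithelium markers, 0.59 for LH and ovulation genes, 0.44 for granulosa identity, 0.57 for endothelial markers, 0.27 for oxidative phosphorylation, 0.25 for immune markers and 0.23 for follicular matrix. None was called with an estimated correlation (adjusted p = 0.356 to 0.687 for the called lists). The theca and stroma, endothelial, surface epithelium, immune and follicular matrix calls ended without KO replicate 2 at 44 h (-0.057, 0.12, 0.043, -0.013 and -0.11). The theca and stroma (0.088), follicular matrix (0.041) and immune (-0.63) calls ended without KO replicate 2 at 0 h. Without the library labelled KO replicate 1 at 44 h camera also called oviduct and ciliated markers higher (2.44) and ribosomal proteins (-0.40), G1/S (-0.24) and G2/M genes (-0.24) lower. The follicular matrix and immune calls ended after median-of-ratios scaling (0.35 and 0.38) and with FPKM of at least 5 in 2 libraries (0.33 and 0.24), the immune call after quantile normalization (0.39) and the endothelial call with FPKM of at least 5 (0.70). Without replicate 2 at 44 h camera also called ribosomal proteins (0.39) and the unfolded protein response (0.18) higher. Adjusted over the list alone, 14 steroidogenesis, 11 FSH-induced and 8 luteal genes were higher and 23 oocyte markers lower, with Nlrp5 the 1 of these called over all genes tested.

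**Figure D2:**
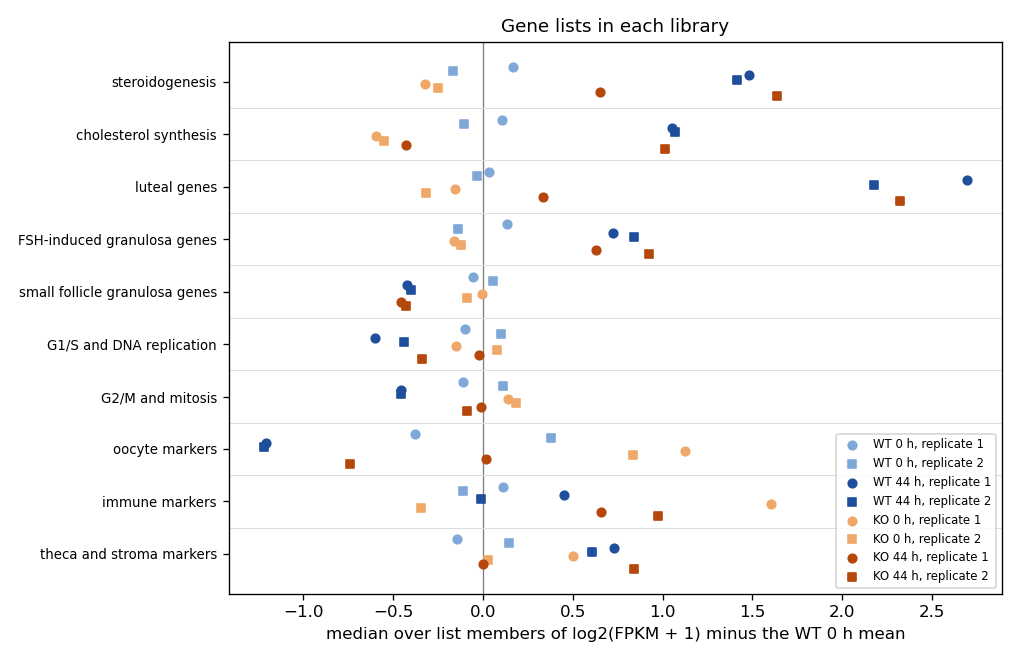
Median of log2(FPKM + 1) over the members of 10 gene lists in each library, minus the WT 0 h mean; circles are replicate 1 and squares replicate 2. For cholesterol synthesis the library labelled KO replicate 1 at 44 h lay at -0.43 and KO replicate 2 at 1.01, with WT at 44 h at 1.05 and 1.07.

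At 44 h, KO lay above WT in oocyte and cell cycle genes, whereas steroid and luteal genes lay below WT in the library labelled KO replicate 1 and near WT in replicate 2. Oocyte markers were higher in 25 of 25 (median 0.86), with Nobox, an oocyte transcription factor, at 55.2 ± 17.8 in KO and 21.2 ± 1.49 in WT. G2/M genes were higher in 40 of 40 (median 0.38), with Nusap1 at 61.4 ± 1.35 and 37.2 ± 4.77. G1/S genes were higher in 34 of 39 (0.36), with Mcm4, a replication helicase subunit, at 56.0 ± 9.69 and 37.2 ± 2.37. Luteal genes had a median of -1.16, steroidogenesis of -0.63, cholesterol synthesis of -0.79 and follicular matrix of -0.32. Without the library labelled KO replicate 1 these medians were -0.046, 0.073, -0.026 and 0.058, and none was called. The oocyte, G2/M and G1/S medians were 0.45, 0.31 and 0.19, each called with the preset correlation and none with an estimated correlation (adjusted p = 0.955, 0.823 and 0.955). In that fit markers of other tissues were called too, with medians of 2.46 for oviduct and ciliated markers, 0.98 for surface epithelium, 0.64 for immune and 0.33 for endothelial markers. Ribosomal proteins (-0.35), oxidative phosphorylation (-0.21) and replication-dependent histones (-0.13) were called lower. Without replicate 2 the oviduct, surface epithelium and endothelial medians were -1.20, -0.94 and -0.59, each called lower, as were theca and stroma markers (-0.62) and LH and ovulation genes (-0.52), and the unfolded protein response was called higher (0.32). Relative to the WT 0 h mean, oviduct and ciliated markers lay at 1.72 and 0.045 in WT at 44 h and at -0.32 and 3.72 in KO at 44 h, in replicate order.

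Camera called 10 lists at 44 h with the preset correlation, among them G2/M (adjusted p = 6.36e-12), oocyte markers (2e-11), cholesterol synthesis (1.01e-07), G1/S (1.4e-05), luteal genes (5.78e-05), follicular matrix (1.03e-04) and steroidogenesis (6.48e-04). The others were immune markers (median 0.59), oxidative phosphorylation (-0.078) and erythroid markers (-1.50, with Hbb-b1, a hemoglobin gene, between 6.39 and 24.8 in KO and 34.9 and 41.7 in WT). With an estimated correlation none was called (adjusted p = 0.85 to 0.853 for the called lists), and adjusted over the list alone 0 members of these lists passed. The erythroid call ended without the library labelled KO replicate 1 (-0.81), KO replicate 2 (-2.41), WT replicate 1 (-1.63) or WT replicate 2 at 44 h (-1.60), and after quantile (-1.59) or median-of-ratios (-1.55) scaling. The immune call ended without KO replicate 2 (0.42) or WT replicate 2 at 44 h (0.45), and the oxidative phosphorylation median was then 0.064 and 0.092. The oxidative phosphorylation call also ended after quantile normalization (-0.0074), with FPKM of at least 5 in 2 libraries (-0.080) and with only the groups compared (-0.078). Cytosolic ribosomal proteins, not called over all libraries (median 0.041), were at 0.43 without replicate 2 and -0.35 without replicate 1. Limma called 3 genes (1 higher, 2 lower), all short RNA entries, with 1340 at an unadjusted p under 0.05. Without the library labelled KO replicate 1 limma called 7 genes, and without replicate 2 it called 801. It called 7 without WT replicate 2 at 44 h and 5 without either WT library at 0 h. Without short RNA entries it called 0, with 1375 at an unadjusted p under 0.05.

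The change after PMSG was then compared between genotypes. G1/S genes fell by a median of 0.53 in WT and were at -0.19 in KO, a difference of 0.41 (36 of 39 members higher), and the differences were 0.25 for G2/M genes and 0.34 for unfolded protein response genes. Luteal genes (-0.97), theca and stroma markers (-0.37) and erythroid markers (-1.41) went the other way. Camera called these 6 lists, and none with an estimated correlation (adjusted p = 0.743 to 0.969 for them). Without the library labelled KO replicate 1 at 44 h the luteal difference was 0.35, and the calls of the unfolded protein response (0.21), theca and stroma markers (-0.052) and erythroid markers (-0.67) were lost. The luteal call also ended without WT replicate 2 at 0 h (-0.84), WT replicate 1 at 44 h (-0.72) or KO replicate 1 at 0 h (-1.02). The theca and stroma call also ended without WT replicate 1 at 0 h (-0.27), WT replicate 1 at 44 h (-0.25) or KO replicate 1 at 0 h (-0.31), and the unfolded protein response call without KO replicate 1 at 0 h (0.20). Without a filter the luteal and theca and stroma calls ended at unchanged medians. The erythroid call also ended without WT replicate 2 at 0 h (-0.49), WT replicate 1 at 44 h (-1.53), KO replicate 1 at 0 h (-0.14) or KO replicate 2 at 44 h (-2.31). The calls of G1/S (0.24) and G2/M genes (0.19) were kept in this and every other fit that left out 1 library. Other lists, not called over all libraries, were called without 1 of the KO libraries at 44 h, and 6 of them with opposite signs in the 2 fits. Without replicate 1 and without replicate 2 the differences were 1.79 and -2.31 for oviduct and ciliated markers, 0.63 and -0.97 for cholesterol synthesis, 0.41 and -0.82 for steroidogenesis, -0.49 and 0.31 for oocyte markers, -0.28 and 0.49 for ribosomal proteins and -0.13 and 0.14 for oxidative phosphorylation, each called. Surface epithelium markers (1.82), FSH-induced genes (0.20) and replication-dependent histones (-0.21) were called without replicate 1. Endothelial markers (-0.73), follicular matrix (-0.63) and LH and ovulation genes (-0.75) were called without replicate 2. With an estimated correlation none of the list calls made without 1 of these libraries held in any of the 5 comparisons (adjusted p = 0.15 to 0.955). Limma called 6 genes in the interaction, all short RNA entries, with 249 at an unadjusted p under 0.05, and 0 without such entries, with 242. It called 11 genes without the library labelled KO replicate 1 at 44 h and 78 without replicate 2.

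Transcripts that fall after PMSG in WT were compared with their fall in KO, with the study's question of mRNA degradation in view. FPKM give levels and not decay rates. Oocyte markers, lower in 25 of 25 in WT at 44 h, were not left out, so a differing share of oocyte RNA may enter these medians. In WT at 0 h they were higher in replicate 2 than in replicate 1 by a median of 0.75. Over a mean of 784 genes lowered in a WT pair, the median change was -0.75 in the other WT pair and -0.85 in KO, a difference of -0.10. The sign turned with the pair used to choose genes. Over 391 genes chosen in WT replicate 1 the change was -0.92 in WT and -0.78 in KO (difference 0.15), and over 1177 chosen in WT replicate 2 it was -0.57 and -0.91 (difference -0.34). Relative to the WT 0 h library of the measured pair, the KO 0 h mean lay at a median of 0 for the first choice and 0.85 for the other. With genes chosen in KO instead (a mean of 936), the median change was -0.62 in the other KO pair and -0.72 in WT, so that WT lay lower by a similar amount (-0.098). The change was -0.64 with the library labelled KO replicate 1 and -1.05 with replicate 2, so the difference from WT was 0.10 or -0.31 by library, and the mean difference was smaller than the spread between the KO libraries (SD 0.289). Over a mean of 762 raised genes the change was 1.12 in WT and 0.81 in KO, with 0.15 in replicate 1 and 1.38 in replicate 2, and for raised genes chosen in KO it was 0.27 in KO and 0.74 in WT. No test was applied to these medians.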

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

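The tests of a mixture, of sequencing depth and of a wrong time or genotype label were chosen after the result was seen; the test of a swap was set before. The difference between genotypes in the PMSG change passed the interaction test for 6 gene lists and 6 genes. The list medians (KO change minus WT change, log2) were -0.97 for luteal genes, 0.41 for G1/S and DNA replication, 0.25 for G2/M and mitosis, 0.34 for the unfolded protein response, -0.37 for theca and stroma markers and -1.41 for erythroid markers, with the preset correlation only. The genes were short RNA entries, for which fitted values against groups listed at 0 depend on the pseudocount: Mir19b-1 (7.24), Mir686 (7.001), Mir763 (-5.67), Mirlet7d (-5.30), Snora69 (4.37) and Snord99 (-11.44). Snord99 was 3833 and 2024 FPKM in WT at 44 h and Mirlet7d 37.4 and 39.5, and both were listed at 0 in all other libraries. Outside 1 group each, Mir19b-1 (84 and 269 in KO at 44 h), Mir763 (39.8 and 62.4 in KO at 0 h) and Snora69 (20.6 and 18.7 in WT at 0 h) were listed at 0, and Mir686 was 0.014 and 0.061 in KO at 0 h and 140.3 to 756 elsewhere. Among 176 genes searched (those named by the rule, those called and the genes of the MHC and genotype accounts), every KO pairing of a 44 h with a 0 h library moved opposite to every WT pairing in a further 6, a difference that was not tested by that criterion: Rpl26 (1.62), Gpc3 (0.56), Atp5s (0.75), Hist2h2ab (-2.30), Mcm3 (0.57) and H2-Q6 (1.20). None of these 6 passed the interaction test over all genes. Random order of the libraries gives 9.78 such genes among the 176 searched. Among the 13688 genes tested it gives 760, where 149 were found. A PMSG response shared by both genotypes lowers such counts, so random order cannot serve as a reference here, and nothing is concluded from them.

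The library labelled KO replicate 1 at 44 h lay at 0.213 on the PMSG axis where replicate 2 lay at 1.03 and KO at 0 h at -0.163 and -0.356. Its relative depth was 1.01 of the median of the other 7, which argues against low depth. A swap would place a 0 h library near 1, where the highest of the 4 was 0.12. A wrong time label would place this library with those at 0 h. Its median position from 0 h (0) to 44 h (1) was taken over genes lower after PMSG in the WT libraries alone, oocyte lists left out. It was 0.526 with KO end points (168 genes) and 0.557 with WT end points (237 genes), against at most 0.0668 and 0.18 in held-out 0 h libraries. The smaller difference was 0.38 (95% bootstrap interval over genes 0.255 to 0.470). Rising genes were left out of that test. In the median they lay near 0 h in this library, with shares of 0.0511 (KO end points) and 0.0398 (WT end points), but not all did. Relative to the WT 0 h mean, the FSH-induced median was 0.63 in this library, against -0.16 and -0.12 in KO at 0 h. The cholesterol synthesis median was -0.43, against -0.60 and -0.55. The test thus argues against a wrong time label by falling genes, and its interval does not measure the spread between libraries. Rising lists were split and were not tested for it. A mixture of responding and non-responding RNA would give the same responding share for genes that rise and genes that fall, but the median share was 0.0511 over 303 rising and 0.675 over 172 falling genes, a difference of 0.62 (95% bootstrap interval over genes 0.572 to 0.660), and 0.57 (0.424 to 0.672) with the WT groups as end points. A wrong genotype label stays open. Over 94 genes that separate the other KO from the WT libraries this library lay at 0.573 between WT (0) and KO (1). This was a difference of -0.090 from the highest held-out WT library (0.663), which met the condition written for a wrong label. The other 3 KO libraries met it too when held out (0.173 to 0.614), so the test did not separate genotypes. Cnot6 (26.7 FPKM) lay in the WT range, while Cnot6l (2.01) lay below all WT libraries (lowest 2.63). H2-Q7 (26.5, against at most 3.85 in WT), Agr3 (22.8, at most 10.5), Serpinb12 (8.90, at most 4.75) and Gm9513 (3.97, listed at 0 in WT), genes singled out with this library among the 8, lay in the KO range. Fetub (115, at most 46.0) did too, 1 gene named by the rule from the comparison at 0 h. An outside sample and a slower or partial response of KO cells, which may also leave rising genes behind falling ones, were not tested and rest on 1 library.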

How the results depend on the processing

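Fits without short RNA entries were chosen after seeing the data; the other alternatives were set before. The counts of called genes (5, 3, 11, 19 and 6 for KO against WT at 0 h and 44 h, PMSG in WT, PMSG in KO and the interaction) moved by over 1.5 times in these cases. KO against WT at 0 h gave 3 without a filter and 8 with robust empirical Bayes, and at 44 h 6 with only the groups compared. PMSG in WT gave 7 after quantile normalization, 945 with only the WT groups and 34 with robust empirical Bayes. PMSG in KO gave 10 with a pseudocount of 0.1, 6 without a filter, 9 with only the KO groups and 35 with robust empirical Bayes. Without short RNA entries limma called 0, 0, 26, 30 and 0, with 1352, 1375, 3351, 2921 and 242 at an unadjusted p under 0.05. The replicate block gave 4, 3, 7, 6 and 5 genes and 52 list calls. After the group means were taken out, the residuals of same-numbered libraries correlated between -0.11 and -0.0068 over genes, so the numbers showed no pairing. Leaving out each library in turn gave 3 to 9, 2 to 801, 4 to 1333, 3 to 1169 and 6 to 78 genes, and 49 to 65 list calls over all comparisons (53 with all libraries). The highest came without KO replicate 2 at 0 h (9), without KO replicate 2 at 44 h (801 and 78) and without KO replicate 1 at 44 h (1333 and 1169). The 53 list calls fell to 0 with an estimated correlation. Of them 43 were kept after median-of-ratios scaling, 44 with FPKM of at least 5 in 2 libraries, 46 after quantile normalization and 50 without a filter. A library left alone in its group was assumed to vary like the other groups. For genes lowered by PMSG in WT the KO minus WT change (-0.10) ranged from -0.31 to 0.10 without single KO libraries. It was -0.32 with genes chosen by a change of at least 2 (log2), and 0.52 over only the 4 genes called lower in WT by limma. For raised genes (-0.31) it ranged from -0.97 to 0.26 without single KO libraries. It was -0.74 with a change of at least 2 (log2), and -2.08 over only the 7 genes called higher. Of these 11 called genes 3 were short RNA entries, and for called genes choice and measurement shared libraries. Signs also turned when single libraries were left out. Cnot6 at 44 h ranged from -0.58 to 0.011, Aif1 at 0 h from -0.034 to 1.61, Fcer1g for PMSG in KO from -0.031 to 1.84 and Hbb-b1 in the interaction from -2.88 to 0.063. Among lists, immune markers ranged from -0.35 to 1.61 at 0 h and from -0.63 to 1.06 for PMSG in KO, oxidative phosphorylation at 44 h from -0.21 to 0.092 (0.064 without KO replicate 2 at 44 h), follicular matrix for PMSG in KO from -0.11 to 0.58 and luteal genes in the interaction from -1.88 to 0.35. Ribosomal proteins at 0 h were at 0 after quantile normalization. Except where stated, the cause was not tested. Fetub kept its direction in every alternative. Relative depth ranged from 0.904 to 1.25, and with FPKM the counting error of single genes is unknown.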

Other observations

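The immune (over both times and at each time), interferon at 44 h and PMSG-fall tests below were chosen after the result was seen, as were the genes named here apart from Fetub; the second oocyte list, the interferon test over both times and the MHC region test were set before. In 293 genes all 4 KO libraries lay above all 4 WT libraries and in 254 below, where random order of the 8 libraries gives 1.43% or 196 genes each. Random order ignores the difference between times and genes that move together, such as the oocyte markers. The counts therefore cannot be read as an excess. Fetub was 78.4 to 115 FPKM in KO and 19.7 to 46.0 in WT, Agr3 20.3 to 32.2 and 4.30 to 10.5, and Serpinb12 8.90 to 16.3 and 2.09 to 4.75. Gm9513, a predicted gene, was 1.91 to 7.15 in KO and listed at 0 in all 4 WT libraries.

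MHC class I genes, which present peptides at the cell surface, lay higher in KO at both times. H2-K1 was 167 to 384 FPKM in KO and 81.5 to 173 in WT, and 12 of 13 class I genes were higher at 0 h and 11 at 44 h, though none passed the test over all genes (H2-Q6 at 44 h, adjusted p = 0.103). An interferon-type response at both times is argued against by 35 interferon-stimulated genes outside the MHC, whose median was -0.022 at 0 h (SE over members 0.0477); at 44 h it was 0.49, from 0.056 in the library labelled KO replicate 1 and 0.86 in replicate 2, so at 44 h alone it stays open, the condition set for it (a median above 0 in each library) being lenient, although H2-K1 was 384 in replicate 1 and 331 in replicate 2. At 44 h immune markers were themselves higher in KO (20 of 21, median 0.59). More immune cell RNA as the source of the whole class I rise is argued against at that time by the immune markers as a set. The immune median lay below the mean of H2-K1 and H2-D1 (1.13), with a difference of -0.36 or lower in each fit that left out 1 of the 4 libraries. The scale of log2(FPKM + 1) damps low markers more than H2-K1 and H2-D1, and single markers differed. Cd52 was 55.9 ± 13.4 FPKM in KO and 25.3 ± 9.03 in WT, and Csf1r 3.75 ± 1.57 and 3.76 ± 1.33. A part of the rise from immune cell RNA stays open at 44 h. At 0 h more immune cell RNA stays open. There the median of 0.57 lay below 0.90 over both KO libraries, with a difference of -1.01 in KO replicate 2 but of 0.46 in KO replicate 1 (1.61 against 1.14). A strain haplotype at the MHC cannot be told apart from an effect of the knockout. The 37 tested genes of the region outside class I differed by a median of 0.18, against 0.214 for expression-matched genes. A one-sided rank permutation against other tested genes, not matched by expression, gave p = 0.9955. The medians met the value set in advance against a haplotype. That value was set too strictly because haplotypes may differ mainly in class I, which the test leaves out.

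The oocyte markers that lay higher in KO may reflect a differing share of oocyte RNA between libraries. A second list of 25 tested oocyte genes had medians of 0.84 at 0 h and 0.82 at 44 h, near the 0.93 and 0.86 of the first list. Within WT at 0 h replicate 2 exceeded replicate 1 by a median of 0.75, in 24 of 25 markers. Any cause that moves oocyte mRNAs in general would move both lists alike. The second list therefore cannot tell a differing share from a higher level of these mRNAs in KO oocytes at both times. The KO change minus WT change had a median of -0.067 (SE over members 0.053, which does not measure the spread between libraries). It was -0.49 without the library labelled KO replicate 1 at 44 h and 0.31 without replicate 2, opposite in sign. Each was below 0.5 of the 44 h difference in that fit (0.45 and 1.24). This argues against a smaller fall after PMSG in KO as the source of most of the 44 h difference. A smaller fall in the library labelled KO replicate 1 stays open. A higher level in KO oocytes was not tested, nor was whether a share differs through cell collection or through the number of oocytes in KO ovaries. A part of the G2/M and G1/S differences from oocyte RNA was not tested either. At 0 h Hmmr was 41.7 and 56.7 FPKM in WT and 120 and 96.3 in KO, in replicate order. Oocyte medians had the same order (-0.38 and 0.38, 1.13 and 0.83). The G2/M median did not in KO (0.14 and 0.19).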
